A study of Mus musculus and Homo sapiens with 21 samples.

How the data were processed

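RNA sequencing of 21 libraries in 7 groups of 3 was used, 12 from mouse epiblast stem cells and 9 from H9 human embryonic stem cells. As deposited by the authors, each species had 1 table of estimated counts per gene, of 56941 mouse and 62754 human genes, not scaled between libraries. The submitters' notes name Trim Galore 0.6.10, HISAT2 2.1.0, StringTie 2.1.7 and DESeq2 1.38.3 and the genome builds GRCh38 and GRCm39, without their roles. The annotation release, the strand, the treatment of reads that map to several places and the way reads of the 2 species were told apart are not given in the sources used here. The values are whole numbers, of which between 28.0% and 31.1% of values from 4 to 60 lay at multiples of 4. How many fragments lie behind a value is not given in the sources used here, so the values were treated as estimates. Totals, in M (mega), ran from 130.1 to 181 in mouse and from 118 to 157 in human libraries. No counting interval was computed, and precision was read from the spread between replicates.

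Libraries were matched to groups by the library names in the labels, and all matched. The numbers of the replicates do not pair libraries: after group means were removed, libraries with the same number correlated across genes at -0.0321 to 0.0510 over 27 pairs, and 13 of these were closest to their own number. With values divided by 4, replicates differed by more than counting error, at a chi-square per gene of 6.17 to 26.7 over 21 pairs, so no library is a copy of another.

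The comparisons, tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except where stated. Each species was fitted once with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), trimmed mean of M values (TMM) scaling, a mean per group and the robust quasi-likelihood F test, two-sided. This tested 23712 mouse and 24165 human genes, with a biological coefficient of variation of 36.7% and 50.3%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons, 5 of them main. The standard error of a log2 fold change is its size over the square root of F. CPM were not log-scaled, and log2 CPM used a prior count of 1. The interaction is the dox effect in co-culture minus that in separate culture.

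The 32 gene lists, written as mouse symbols with their human orthologs, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided and adjusted over lists, where at least 5 members were tested. Each was also tested with an estimated correlation, and with fry, which tests whether a list's genes move 1 way on balance. A further 4 lists (macrophage, immediate early, motile cilium, and posterior and caudal axis genes) were made after the values were seen. Named genes were, among called genes with a mean log2 CPM of at least 2 and no overlap between the replicates of the groups (which chance gives in 10% of genes), the 8 largest each way in a main comparison and 4 in another. To these came the 3 members with the smallest p of up to 6 called lists in main comparisons and 9 fixed genes: Pou5f1, Sox2, Nanog, Tbxt (listed as T in the mouse table), Mavs, Isg15, Cdkn1a, Atf4, Col1a1 and their orthologs. Predicted, clone-named and unnamed genes were left out of the largest, 460 mouse and 21880 human entries having no symbol. List members were also named as examples. Some genes that met the rule are not reported here.

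The alternatives were DESeq2 1.42.0, DESeq2's size factors, upper quartile scaling, no filter, a filter of 10 CPM in 3 libraries, a test against a fold of 1.5 (glmTreat), a fit of only the groups compared, the replicate number as a block, and each library left out. Counts divided by 4 and library totals alone were added after the data were seen. Where a library was left out, the fit pooled the spread over groups.

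The procedure was tested on simulations with the observed means and spread, 66 or 67 changed genes per fold and no other effects. For folds of 1.5, 2 and 4, edgeR recovered 52.2, 49.2 and 68.2% of changed genes for mouse dox in separate culture, 16.4, 44.8 and 63.6% for the interaction and 20.9, 50.8 and 74.2% for human dox in co-culture. Among its calls 5.60, 5.32 and 4.72% were false, and by DESeq2 29.4, 32.0 and 35.6%. The changed list of 25 genes was always called and 0 of 31 unchanged ones were. Correlated genes or more changes may alter these rates.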

Results

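RNA was sequenced from mouse epiblast stem cells and human embryonic stem cells after 4 days alone or together, with or without doxycycline (dox). The mouse cells, of the primed, post-implantation type, were derived from C57BL/6 mice, and the human cells were the established line H9. By the series title the mouse cells were stable lines in which dox induces Cas13, an enzyme that a guide RNA directs to cleave RNA. The labels name no guide or target. Both species grew on mouse embryonic fibroblast feeders, and co-cultures were seeded with 4 human cells to 1 mouse cell. The mouse table held 12 libraries in 4 groups of 3: separate culture and co-culture, each with and without dox. The human table held 9 libraries in 3 groups of 3: separate culture without dox, and co-culture with and without it. No human cells were given dox in separate culture, and every culture given dox held the Cas13 mouse cells. The labels do not state that replicates were separate cultures, so the p-values measure the spread between samples.

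Total estimated counts per library, in M (mega) and in the order of replicates 1 to 3, were 133, 141 and 181 for mouse separate culture without dox and 131, 139 and 149 with dox. Mouse co-cultures had 134, 130.1 and 132 M without dox and 161, 133 and 147 M with dox. Human separate cultures had 132, 124 and 129 M. Human co-cultures had 143, 157 and 127 M without dox and 118, 139 and 124 M with dox. Replicates of 1 group correlated across genes at Pearson r of 0.911 or more on log2 CPM (counts scaled to the library total), and the lowest value was between human co-culture dox-free replicates 1 and 2. On the first principal component of the human libraries, which held 29.4% of the variance, these 3 co-culture dox-free libraries lay at 148, 153 and 68.5, and the separate cultures between -106 and -101. Values are log2 fold changes ± standard error (SE) from edgeR or mean CPM ± standard deviation (SD), with n = 3 libraries per group throughout, and adjusted p for a gene list is from camera, a test of the list against all other genes. Beside the counts over all genes tested, list alone gives the counts adjusted over the list alone.

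**Figure D1:**
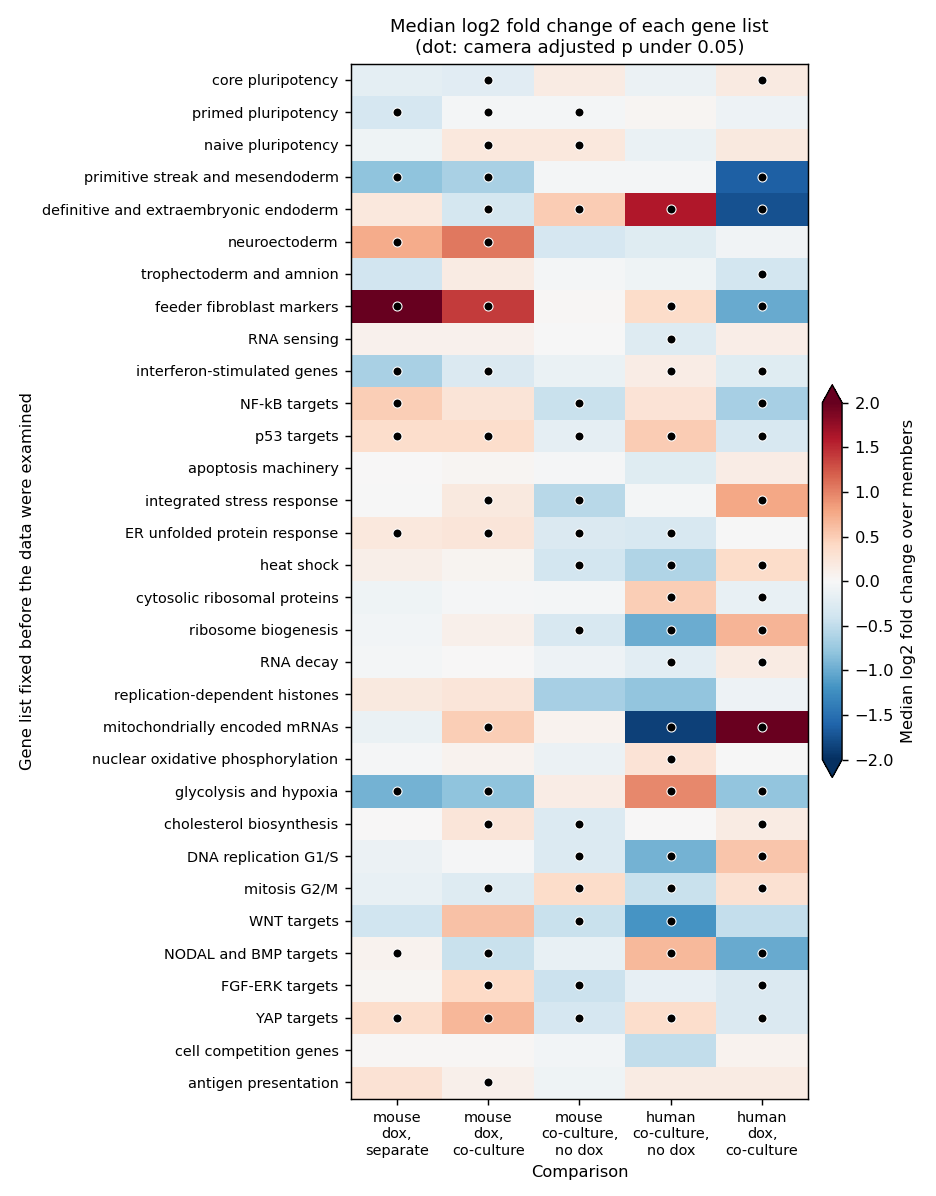
Median log2 fold change of each of the 32 gene lists (vertical axis) in the 5 main comparisons (horizontal axis), with colour from lower to higher and a dot where the camera adjusted p was under 0.05. Glycolysis and hypoxia genes had medians of -0.94 and -0.81 with dox in mouse cells.

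What dox changed in mouse cells grown alone was asked first. Collagen and other matrix genes rose together: Col3a1, a fibrillar collagen, went from 4.41 ± 0.229 to 100.2 ± 7.49 CPM (4.50 ± 0.083). Glycolytic and hypoxia-induced genes fell, among them Ndrg1, a gene induced by low oxygen, from 287 ± 3.35 to 71.8 ± 2.06 CPM, and Pgk1, a glycolytic kinase, from 2959.9 ± 96.4 to 1083 ± 51.0 CPM. The genes with the largest falls included several of motile cilia: Cfap65 and Cfap95, Dnaaf11, a dynein assembly factor, Drc7, of the dynein regulatory complex, Iqub and Ak7, with log2 fold changes between -4.15 and -3.27. Sox1, a neuroectoderm transcription factor, rose from 1.61 ± 0.588 to 22.2 ± 1.08 CPM.

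Other genes with large increases were Lrrn3 (6.04 ± 0.28), a leucine-rich repeat membrane protein, Tfpi2 (4.35 ± 0.28), a protease inhibitor, the cadherin Cdh6 (4.35 ± 0.34), Pomc (4.27 ± 0.13), the precursor of melanocortin peptides, the cartilage collagen Col9a1 (4.12 ± 0.26) and Olr1 (3.90 ± 0.20), a receptor for oxidised lipoprotein. Large decreases were also seen for Cracdl (-3.67 ± 0.32) and for Grin1 (-3.61 ± 0.12), an NMDA receptor subunit. Of 20 tested feeder fibroblast and matrix markers, 20 were higher, 0 lower and 0 did not pass (list alone 20 and 0), with a median of 2.104 (adjusted p = 3.5e-89). Members included Col1a2 at 3.08 ± 0.068 and Col1a1 at 2.79 ± 0.071. Feeder cells are mouse cells, and their RNA was not measured apart. Macrophage markers, a list made after the values were seen, were higher for 10 and lower for 3 of 24 (median 0.77, adjusted p = 0.0017 over the lists added, adjusted p = 0.11 with an estimated correlation), and in co-culture for 6 and 6 (median 0.047, adjusted p = 0.34). The glycolysis and hypoxia genes had 20 lower, 0 higher and 4 not passing of 24 tested (list alone 20 and 0), with a median of -0.94 (adjusted p = 6.6e-64). Members included the kinase Pdk1 at -1.49 ± 0.053. Among interferon-stimulated genes, 15 of 26 were lower, 1 higher and 10 did not pass (list alone 16 and 1), with a median of -0.64 (adjusted p = 1.0e-12). Usp18 (-2.26 ± 0.070), a brake on interferon signalling, and Bst2 (-1.07 ± 0.072) were lower. Of 16 tested neuroectoderm genes, 9 were higher, 2 lower and 5 did not pass (list alone 9 and 2), with a median of 0.74 (adjusted p = 5.3e-04). The p53 targets had 13 higher, 2 lower and 7 not passing of 22 tested (list alone 13 and 2), with a median of 0.36 (adjusted p = 8.2e-04). Members included Cdkn1a, a cell cycle inhibitor, at 0.56 ± 0.065.

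The NODAL and BMP targets had 6 higher, 3 lower and 6 not passing of 15 tested (list alone 6 and 3), with a median of 0.064 (adjusted p = 5.5e-06). The call was lost at adjusted p = 0.055 with an estimated correlation. Members that rose included the NODAL inhibitors Lefty1 (2.04 ± 0.070) and Lefty2 (2.15 ± 0.085). Among primitive streak and mesendoderm genes, 10 of 18 were lower, 1 higher and 7 did not pass (list alone 10 and 1), with a median of -0.81 (adjusted p = 3.0e-05). With an estimated correlation its adjusted p was 0.083. The transcription factors Eomes (-1.65 ± 0.068), Foxa2 (-1.04 ± 0.079) and Sp5 (-1.56 ± 0.16) were lower. Of 19 tested NF-kB targets, 9 were higher, 2 lower and 8 did not pass (list alone 12 and 2), with a median of 0.50 (adjusted p = 9.8e-05). The cytokines Csf1 (1.75 ± 0.085) and Ccl2 (1.44 ± 0.13) and the inhibitor Tnfaip3 (1.12 ± 0.082) were higher. Among apoptosis genes, 6 of 24 were lower, 5 higher and 13 did not pass (list alone 7 and 5), with a median of 0.010 (adjusted p = 0.92). The mean of this list was -0.0086 and its test pointed higher. Of the genes fixed beforehand, Pou5f1 (-0.45 ± 0.053), T, the mesoderm factor also called Tbxt (-0.45 ± 0.048), and Isg15 (-0.95 ± 0.13) were lower, and Sox2 (0.31 ± 0.048) and Nanog (0.35 ± 0.043) were higher. Mavs, the adaptor of RNA sensing, was at -0.062 ± 0.11 (adjusted p = 0.76) and Atf4, of the integrated stress response, at 0.0057 ± 0.049 (adjusted p = 0.96).

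In the test of all genes, 6723 of 23712 genes passed, 3383 higher and 3340 lower, of which 948 and 982 changed at least 2-fold, with 42.8% to 52.4% higher over 4 scalings. The ER unfolded protein response genes (11 higher and 1 lower of 18, list alone 12 and 1, median 0.21) and the YAP targets (9 higher and 3 lower of 16, list alone 11 and 3, median 0.35) were called higher. The primed pluripotency genes (10 lower and 4 higher of 16, list alone 10 and 5, median -0.34) were called lower. Camera gave these 3 lists adjusted p from 3.3e-04 to 0.0053. With an estimated correlation, adjusted p was 0.077 for the primed pluripotency genes, 0.083 for the ER unfolded protein response genes and 0.093 for the YAP targets. The remaining 20 lists were not called, at adjusted p of 0.052 or more. Among genes at 10 CPM or more, the neuroectoderm (adjusted p = 0.053), p53 target (0.053) and ER unfolded protein response (0.052) lists lost their calls. The effects of dox and of Cas13 could not be separated in any dox comparison.

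**Figure D2:**
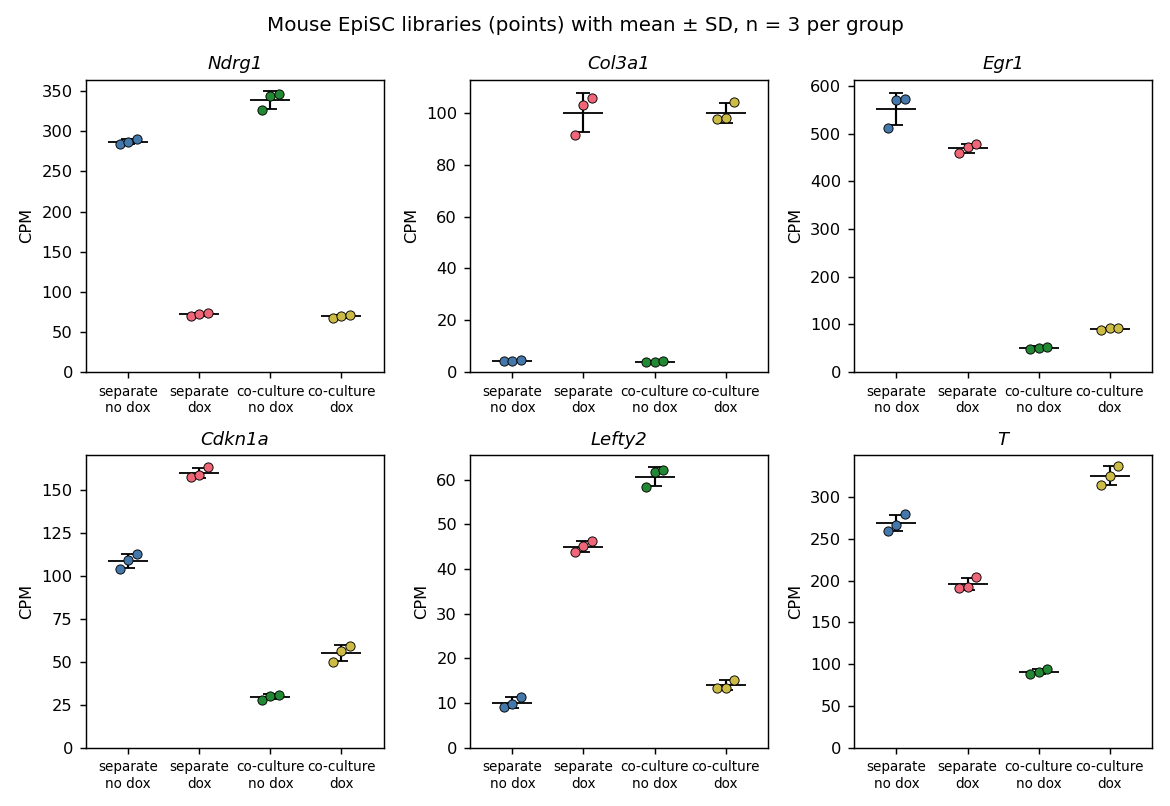
CPM (vertical axes) of Ndrg1, Col3a1, Egr1, Cdkn1a, Lefty2 and T in each mouse library, by group (horizontal axes), with points for libraries and the mean ± SD. Col3a1 was at 100.2 ± 7.49 CPM in separate culture with dox and 100.01 ± 3.83 in co-culture with dox.

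The same was asked of mouse cells grown with human cells. Dox again went with more Col3a1 (3.90 ± 0.329 to 100.01 ± 3.83 CPM) and less Ndrg1 (339 ± 10.9 to 69.3 ± 2.38 CPM). Arg1, the arginase of the urea cycle, rose from 0.566 ± 0.0668 to 33.0 ± 1.88 CPM, and Pomc from 1.42 ± 0.206 to 57.8 ± 3.41 CPM. T rose from 91.0 ± 3.18 to 325 ± 11.6 CPM, and Sox1 from 2.13 ± 0.352 to 41.9 ± 2.05 CPM. Tdgf1, the NODAL co-receptor, fell from 502 ± 6.12 to 126 ± 3.37 CPM.

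Further large increases were Sprr2a2 (6.07 ± 0.24) and Sprr2a1 (6.00 ± 0.27), near-identical genes of the cornified envelope whose reads cannot be assigned with certainty, Lrrn3 (4.91 ± 0.26) and Col9a1 (4.69 ± 0.26), and Hoxb3os (5.06 ± 0.96), an antisense transcript (the strand of the libraries is not given). Large decreases were Tuba8 (-3.98 ± 0.17), an alpha-tubulin, C3 (-3.22 ± 0.15), a complement component, Iqub (-3.09 ± 0.21), the glycosyltransferase Galnt6 (-3.03 ± 0.19), Gata4 (-2.99 ± 0.14), an endoderm and heart transcription factor, Espn (-2.99 ± 0.15), an actin bundling protein, and Grin1 (-2.87 ± 0.12). Marco, a macrophage scavenger receptor, was at 1.30 ± 0.301 CPM without and 0.0179 ± 0.0311 CPM with dox. Of 24 tested glycolysis and hypoxia genes, 20 were lower, 0 higher and 4 did not pass (list alone 20 and 0), with a median of -0.81 (adjusted p = 1.4e-52). Members included Pgk1 at -1.30 ± 0.046 and Pdk1 at -1.26 ± 0.053. The feeder fibroblast and matrix markers had 17 higher, 0 lower and 3 not passing of 20 tested (list alone 18 and 0), with a median of 1.40 (adjusted p = 2.5e-46). Members included Col1a1 at 1.97 ± 0.069 and Acta2, smooth muscle actin, at 2.92 ± 0.12. Among YAP targets, 13 of 16 were higher, 1 lower and 2 did not pass (list alone 13 and 1), with a median of 0.66 (adjusted p = 1.2e-10). Ccn2 (1.09 ± 0.045), Ccn1 (0.66 ± 0.044) and Amotl2 (0.65 ± 0.047) were higher. Of 15 tested NODAL and BMP targets, 8 were lower, 2 higher and 5 did not pass (list alone 10 and 2), with a median of -0.44 (adjusted p = 5.4e-08). Lefty2 was lower (-2.11 ± 0.085) and Id2 was higher (1.23 ± 0.091). The neuroectoderm genes had 11 higher, 2 lower and 3 not passing of 16 tested (list alone 11 and 2), with a median of 1.05 (adjusted p = 7.3e-08). The transcription factor Irx3 (1.48 ± 0.088) and the adhesion molecule Ncam1 (1.18 ± 0.084) were higher.

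Among cholesterol biosynthesis genes, 16 of 22 were higher, 1 lower and 5 did not pass (list alone 17 and 1), with a median of 0.24 (adjusted p = 1.2e-07). Members included the enzyme Hsd17b7 at 1.56 ± 0.054. The naive pluripotency genes (5 higher and 3 lower of 13, list alone 5 and 3, median 0.22) and the p53 targets (12 higher and 1 lower of 22, list alone 14 and 1, median 0.35) were called higher. The integrated stress response genes (15 higher and 3 lower of 25, list alone 15 and 4, median 0.20) and the ER unfolded protein response genes (12 higher and 0 lower of 18, list alone 13 and 0, median 0.24) were called higher. The mitochondrially encoded mRNAs (6 higher and 0 lower of 13, list alone 6 and 0, median 0.49) and the FGF-ERK targets (9 higher and 2 lower of 16, list alone 11 and 3, median 0.40) were called higher. The antigen presentation genes (6 higher and 0 lower of 13, list alone 6 and 0, median 0.094) were called higher. The core pluripotency genes (7 lower and 2 higher of 15, list alone 7 and 3, median -0.22) and the primed pluripotency genes (6 lower and 4 higher of 16, list alone 6 and 5, median -0.032) were called lower. The primitive streak and mesendoderm genes (9 lower and 4 higher of 18, list alone 9 and 4, median -0.64) and the definitive and extraembryonic endoderm genes (5 lower and 2 higher of 15, list alone 6 and 3, median -0.36) were called lower. The interferon-stimulated genes (12 lower and 4 higher of 26, list alone 12 and 4, median -0.29) and the mitosis genes (12 lower and 0 higher of 22, list alone 15 and 0, median -0.26) were called lower. Camera gave these 13 lists adjusted p from 2.9e-07 to 0.012. Adjusted p with an estimated correlation was 0.060 for the primed pluripotency genes, 0.062 for the primitive streak and mesendoderm genes, 0.44 for the mitochondrially encoded mRNAs and 0.14 for the antigen presentation genes. The test differed in sign from the median or mean for the primitive streak and mesendoderm genes (mean 0.30). The remaining 13 lists were not called, at adjusted p of 0.070 or more. Among the fixed genes, Pou5f1 (-0.28 ± 0.053) and Nanog (-0.22 ± 0.043) were lower and Sox2 (0.25 ± 0.048), Cdkn1a (0.89 ± 0.065) and Atf4 (0.36 ± 0.049) higher, while Mavs (-0.24 ± 0.11, adjusted p = 0.11) and Isg15 (-0.25 ± 0.13, adjusted p = 0.20) did not pass. With the filter of 10 CPM, Mavs passed at adjusted p = 0.049. In this comparison 6723 of 23712 genes passed, 3631 higher and 3092 lower, of which 1053 and 936 changed at least 2-fold, with 46.2% to 54.1% higher over 4 scalings. With the filter of 10 CPM in 3 libraries, the antigen presentation genes (adjusted p = 0.068) lost their call.

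Whether the dox effect was the same with and without human cells was asked of all mouse genes. Lefty2 moved in opposite directions, 2.15 ± 0.085 with dox in separate culture and -2.11 ± 0.085 in co-culture, a difference of -4.27 ± 0.12. T also moved in opposite directions, -0.45 ± 0.048 and 1.84 ± 0.049, a difference of 2.29 ± 0.069. The dox effect was higher in co-culture for the fatty acid receptor Cd36 (3.81 ± 0.28), the apelin receptor Aplnr (3.22 ± 0.10), Arg1 (3.11 ± 0.18) and Sprr2a2 (3.09 ± 0.29), and lower for Tfpi2 (-4.18 ± 0.37) and Pga5, a pepsinogen (-3.57 ± 0.16). Marco also passed (-3.29 ± 0.72), from a level of 0.0179 ± 0.0311 CPM in co-culture with dox.

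Of 15 NODAL and BMP targets, 8 had a lower and 2 a higher dox effect in co-culture and 5 did not pass (list alone 9 and 2), with a median of -0.74 (adjusted p = 7.4e-41). Of 20 feeder fibroblast and matrix markers, 12 had a lower and 0 a higher dox effect in co-culture and 8 did not pass (list alone 14 and 0), with a median of -0.66 (adjusted p = 8.8e-15). Of 15 definitive and extraembryonic endoderm genes, 5 had a lower and 1 a higher dox effect in co-culture and 9 did not pass (list alone 5 and 1), with a median of -0.93 (adjusted p = 1.2e-06). In what follows, higher and lower refer to the dox effect in co-culture minus that in separate culture. The neuroectoderm genes (5 higher and 1 lower of 16, list alone 5 and 1, median 0.31) and the interferon-stimulated genes (5 higher and 1 lower of 26, list alone 9 and 1, median 0.30) were called higher. The integrated stress response genes (12 higher and 1 lower of 25, list alone 13 and 2, median 0.20) and the mitochondrially encoded mRNAs (1 higher and 0 lower of 13, list alone 5 and 0, median 0.63) were called higher. The cholesterol biosynthesis genes (9 higher and 0 lower of 22, list alone 14 and 0, median 0.20) and the WNT targets (5 higher and 1 lower of 13, list alone 5 and 2, median 0.33) were called higher. The FGF-ERK targets (4 higher and 1 lower of 16, list alone 5 and 2, median 0.16) and the YAP targets (4 higher and 1 lower of 16, list alone 4 and 1, median 0.044) were called higher. The core pluripotency genes (2 lower and 1 higher of 15, list alone 2 and 2, median 0.0038) and the NF-kB targets (7 lower and 0 higher of 19, list alone 7 and 1, median -0.12) were called lower. Camera gave these 10 lists adjusted p from 1.2e-08 to 0.016. Calls not held with an estimated correlation were at adjusted p of 0.057 for the core pluripotency genes, 0.057 for the neuroectoderm genes, 0.36 for the mitochondrially encoded mRNAs and 0.13 for the YAP targets. The test differed in sign from the median or mean for the core pluripotency genes (mean -0.19). The remaining 19 lists were not called, at adjusted p of 0.050 or more. Macrophage markers were lower too, 6 lower and 0 higher of 24 (median -0.83, adjusted p = 4.1e-08 over the lists added). Among the fixed genes, Nanog (-0.57 ± 0.061) and Col1a1 (-0.83 ± 0.095) had a lower and Isg15 (0.70 ± 0.19), Cdkn1a (0.33 ± 0.091) and Atf4 (0.35 ± 0.070) a higher effect in co-culture, and Pou5f1 (0.17 ± 0.075, adjusted p = 0.21), Sox2 (-0.063 ± 0.068, adjusted p = 0.69) and Mavs (-0.18 ± 0.15, adjusted p = 0.58) did not pass.

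The interaction passed for 2054 of 23712 genes, 1155 with a higher and 899 with a lower effect in co-culture, 339 and 272 of them at least 2-fold, with 49.3% to 56.4% higher over 4 scalings. By adjusted p in parentheses, Isg15 no longer passed without co-culture dox replicate 1 (0.088), co-culture dox replicate 2 (0.068), co-culture dox-free replicate 2 (0.079), co-culture dox-free replicate 3 (0.067), separate dox replicate 1 (0.056), separate dox replicate 2 (0.088), separate dox-free replicate 1 (0.073) and separate dox-free replicate 3 (0.092). Cdkn1a no longer passed without co-culture dox replicate 1 (0.10), co-culture dox replicate 3 (0.086), co-culture dox-free replicate 1 (0.10), co-culture dox-free replicate 2 (0.056), separate dox replicate 1 (0.081), separate dox replicate 2 (0.089), separate dox-free replicate 1 (0.075), separate dox-free replicate 2 (0.053) and separate dox-free replicate 3 (0.099), nor with library totals alone (0.052) or no filter (0.066).

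The dox effects of the 2 cultures, which share no library, correlated across 23712 genes at Pearson r = 0.333 and Spearman rho = 0.453, and at r = 0.559 among the 9275 genes called in either; genes are not independent replicates. Of 4171 genes called in both, 3964 (95.04%) had the same direction. Higher in both were 2100 genes, against 518 for independent lists, and lower in both were 1864, against 436. The interaction passed for 2025 of the 9275 genes, including all 207 genes called in opposite directions. Across the genes tested r was 0.687 with the filter of 10 CPM and 0.246 to 0.263 without any 1 library, fits whose genes may differ.

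What human neighbours changed in mouse cells was asked without dox. Genes that respond within minutes to growth factors or handling were far lower in co-culture: Egr1 fell from 551 ± 34.5 to 50.6 ± 3.09 CPM, Fos from 533 ± 7.02 to 80.7 ± 6.71 CPM and Atf3 from 264 ± 9.64 to 17.6 ± 1.63 CPM. Cdkn1a fell from 109 ± 4.22 to 29.7 ± 1.65 CPM. Lefty2 rose from 10.1 ± 1.15 to 60.7 ± 2.04 CPM, and mitosis genes such as Nusap1, a spindle protein, were higher (100.03 ± 6.83 to 179.6 ± 4.85 CPM). T fell from 269 ± 10.1 to 91.0 ± 3.18 CPM.

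Other large decreases were the immediate early genes Npas4 (-7.86 ± 0.55), Egr4 (-7.58 ± 0.30), Egr3 (-6.63 ± 0.20) and Egr2 (-6.08 ± 0.31), the AP-1 gene Fosl1 (-5.63 ± 0.51), Klf4 (-4.92 ± 0.19), Sprr1a (-6.46 ± 1.05) of the cornified envelope, and Mmp12 (-4.59 ± 0.24), the macrophage elastase. Further increases were Pga5 (2.34 ± 0.12) and Tbc1d30 (2.15 ± 0.15), the ectodysplasin receptor Edar (2.02 ± 0.19), the zinc finger genes Rsl1 (1.87 ± 0.16) and Zfp759 (1.79 ± 0.23), the insulin receptor substrate Irs4 (1.83 ± 0.11) and the non-coding Mir100hg (1.77 ± 0.24). Of 25 tested integrated stress response genes, 23 were lower, 1 higher and 1 did not pass (list alone 23 and 1), with a median of -0.55 (adjusted p = 4.7e-38). Sesn2 (-1.82 ± 0.050) and the phosphatase subunit Ppp1r15a (-2.39 ± 0.073) were lower. The FGF-ERK targets had 9 lower, 2 higher and 5 not passing of 16 tested (list alone 9 and 2), with a median of -0.43 (adjusted p = 6.7e-27). Members included the phosphatase Dusp5 at -3.55 ± 0.079. Among p53 targets, 10 of 22 were lower, 4 higher and 8 did not pass (list alone 11 and 5), with a median of -0.18 (adjusted p = 7.2e-11). Members included the kinase Plk2 at -2.39 ± 0.078. Of 22 tested mitosis genes, 15 were higher, 1 lower and 6 did not pass (list alone 15 and 1), with a median of 0.37 (adjusted p = 4.2e-09). Ccnb1 (0.56 ± 0.043) and Cdk1 (0.63 ± 0.051), the mitotic cyclin and its kinase, were higher. The YAP targets had 9 lower, 1 higher and 6 not passing of 16 tested (list alone 9 and 1), with a median of -0.34 (adjusted p = 1.3e-08). Ccn1 (-2.03 ± 0.045), Amotl2 (-1.73 ± 0.048) and Ccn2 (-0.61 ± 0.045) were lower. Among cholesterol biosynthesis genes, 13 of 22 were lower, 1 higher and 8 did not pass (list alone 14 and 1), with a median of -0.27 (adjusted p = 1.4e-07). Hsd17b7 (-0.95 ± 0.053) and Insig1 (-0.53 ± 0.037) were lower.

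The primed pluripotency genes (6 higher and 4 lower of 16, list alone 6 and 4, median -0.035) and the definitive and extraembryonic endoderm genes (5 higher and 1 lower of 15, list alone 5 and 1, median 0.50) were called higher. The naive pluripotency genes (4 lower and 1 higher of 13, list alone 4 and 1, median 0.22) and the NF-kB targets (12 lower and 1 higher of 19, list alone 12 and 1, median -0.45) were called lower. The ER unfolded protein response genes (12 lower and 1 higher of 18, list alone 12 and 1, median -0.28) and the heat shock genes (11 lower and 1 higher of 15, list alone 12 and 1, median -0.37) were called lower. The ribosome biogenesis genes (20 lower and 2 higher of 28, list alone 22 and 2, median -0.33) and the DNA replication genes (17 lower and 0 higher of 23, list alone 19 and 0, median -0.27) were called lower. The WNT targets (7 lower and 3 higher of 13, list alone 7 and 3, median -0.45) were called lower. Camera gave these 9 lists adjusted p from 1.4e-07 to 0.021. With an estimated correlation, adjusted p was 0.089 for the primed pluripotency genes and 0.054 for the WNT targets. The test differed in sign from the median or mean for the primed pluripotency genes (mean 0.15) and the naive pluripotency genes (mean -0.60). The remaining 17 lists were not called, at adjusted p of 0.051 or more. Macrophage markers were lower for 23 of 24 genes with a median of -3.40 (adjusted p = 3.8e-51), and the feeder fibroblast markers had a median of 0.017. Of the fixed genes, Pou5f1 (-0.20 ± 0.053), Sox2 (-0.57 ± 0.049), Isg15 (-0.79 ± 0.13) and Atf4 (-0.75 ± 0.050) were lower and Nanog (0.68 ± 0.043) and Mavs (0.71 ± 0.11) higher, and Col1a1 (-0.037 ± 0.067, adjusted p = 0.75) did not pass. The call of Pou5f1 was lost without separate dox-free replicate 3 (adjusted p = 0.065) and with library totals alone (adjusted p = 0.11). In all, 7230 of 23712 genes passed, 3222 higher and 4008 lower, of which 569 and 1087 changed at least 2-fold, with 44.2% to 59.0% higher over 4 scalings. With the filter of 10 CPM in 3 libraries, the primed pluripotency genes (adjusted p = 0.061) lost their call.

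The same comparison with dox present showed early response and macrophage genes lower again. The transcription factors Egr4 and Npas4 were at -5.35 ± 0.26 and -4.93 ± 0.45, and C1qa, a complement component made by macrophages, fell from 38.2 ± 4.77 to 1.22 ± 0.471 CPM. Marco was at 2.58 ± 0.530 CPM in separate culture and 0.0179 ± 0.0311 in co-culture. Higher in co-culture were Ppp1r3c, a glycogen regulator (2.28 ± 0.21), Sez6 (2.15 ± 0.18), Doc2a (2.06 ± 0.13), a calcium sensor of vesicle release, and Catsperg1 (1.90 ± 0.13), of a sperm calcium channel. T rose from 196 ± 7.24 to 325 ± 11.6 CPM, the reverse of its change without dox.

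Among NODAL and BMP targets, 12 of 15 were lower, 1 higher and 2 did not pass (list alone 13 and 1), with a median of -0.84 (adjusted p = 1.6e-27). The integrated stress response genes had 20 lower, 1 higher and 4 not passing of 25 tested (list alone 20 and 2), with a median of -0.39 (adjusted p = 3.8e-20). Of 19 tested NF-kB targets, 13 were lower, 0 higher and 6 did not pass (list alone 13 and 1), with a median of -0.72 (adjusted p = 3.3e-14). Among replication-dependent histone genes, 5 of 23 were lower, 0 higher and 18 did not pass (list alone 5 and 0), with a median of -0.58 (adjusted p = 0.025). The call was lost at adjusted p = 0.18 with an estimated correlation. Of 16 tested cell competition genes, 9 were lower, 4 higher and 3 did not pass (list alone 9 and 4), with a median of -0.24 (adjusted p = 0.029). With an estimated correlation its adjusted p was 0.068. The primed pluripotency genes (5 higher and 1 lower of 16, list alone 6 and 1, median 0.072) and the interferon-stimulated genes (8 higher and 2 lower of 26, list alone 9 and 2, median 0.14) were called higher. The mitochondrially encoded mRNAs (9 higher and 0 lower of 13, list alone 12 and 0, median 0.64) and the glycolysis and hypoxia genes (12 higher and 2 lower of 24, list alone 12 and 2, median 0.19) were called higher. The mitosis genes (13 higher and 0 lower of 22, list alone 13 and 0, median 0.20) were called higher. The naive pluripotency genes (5 lower and 3 higher of 13, list alone 5 and 3, median -0.25) and the trophectoderm and amnion genes (5 lower and 1 higher of 16, list alone 6 and 1, median -0.47) were called lower. The feeder fibroblast and matrix markers (12 lower and 0 higher of 20, list alone 15 and 0, median -0.73) and the p53 targets (11 lower and 2 higher of 22, list alone 11 and 3, median -0.25) were called lower. The ER unfolded protein response genes (11 lower and 0 higher of 18, list alone 14 and 0, median -0.27) and the heat shock genes (11 lower and 0 higher of 15, list alone 11 and 0, median -0.37) were called lower. The ribosome biogenesis genes (16 lower and 0 higher of 28, list alone 19 and 1, median -0.18) and the DNA replication genes (14 lower and 0 higher of 23, list alone 14 and 1, median -0.20) were called lower. The FGF-ERK targets (9 lower and 3 higher of 16, list alone 9 and 3, median -0.52) and the YAP targets (6 lower and 1 higher of 16, list alone 7 and 1, median -0.26) were called lower. Camera gave these 15 lists adjusted p from 2.2e-17 to 0.014. Adjusted p with an estimated correlation was 0.063 for the trophectoderm and amnion genes, 0.068 for the interferon-stimulated genes, 0.37 for the mitochondrially encoded mRNAs, 0.068 for the glycolysis and hypoxia genes and 0.069 for the YAP targets. The remaining 12 lists were not called, at adjusted p of 0.31 or more. The macrophage markers were lower for 22 of 24 genes, with a median of -4.11 (adjusted p = 1.4e-85). Among the fixed genes, Sox2 (-0.63 ± 0.048), Cdkn1a (-1.54 ± 0.066), Atf4 (-0.40 ± 0.049) and Col1a1 (-0.86 ± 0.067) were lower and Mavs (0.53 ± 0.11) higher. Pou5f1 (-0.032 ± 0.053, adjusted p = 0.73), Nanog (0.11 ± 0.043, adjusted p = 0.064) and Isg15 (-0.089 ± 0.13, adjusted p = 0.70) did not pass. Nanog did pass without separate dox replicate 3 (adjusted p = 0.031), by DESeq2 (0.041), with the filter of 10 CPM (0.037) and with library totals alone (0.0062). In all, 6572 of 23712 genes passed, 3230 higher and 3342 lower, of which 537 and 983 changed at least 2-fold, with 47.4% to 59.2% higher over 4 scalings. The call of the replication-dependent histone genes was lost without co-culture dox replicate 2 (adjusted p = 0.059) and without separate dox replicate 3 (adjusted p = 0.073). Among genes at 10 CPM or more, the cell competition (adjusted p = 0.16) and histone (no adjusted p) lists lost their calls.

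What mouse neighbours changed in human cells was asked without dox. Glycolytic and hypoxia-induced genes rose: NDRG1 went from 8.17 ± 0.359 to 172 ± 22.9 CPM and PGK1 from 631 ± 5.70 to 2429 ± 233 CPM. Every mitochondrially encoded mRNA fell, among them MT-CO3, a subunit of cytochrome oxidase, from 6132 ± 295 to 1674 ± 73.0 CPM. WNT target genes fell, with AXIN2, a feedback inhibitor of the pathway, going from 139.7 ± 3.08 to 32.4 ± 2.09 CPM, and TBXT, the mesoderm factor, from 153 ± 6.74 to 34.2 ± 3.62 CPM. CDKN1A rose from 37.2 ± 1.36 to 89.0 ± 6.18 CPM while DNA replication genes fell.

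The largest increases were NRN1 (6.88 ± 0.53), neuritin, UPK1A (5.47 ± 0.26), a uroplakin, CD48 (5.34 ± 0.30), a leukocyte surface protein, SHISA2 (5.10 ± 0.21), an inhibitor of WNT and FGF receptor maturation, LOX (5.09 ± 0.48), a collagen crosslinking enzyme, the actin capping protein TMOD1 (5.02 ± 0.78), GATA6-AS1 (4.93 ± 0.20), an antisense transcript, and the receptor ERBB4 (4.64 ± 0.26). Among decreases, the WNT-responsive CDX1 was at -4.75 ± 0.28, the R-spondin RSPO3 at -4.52 ± 0.79 and the early response gene FOSB at -4.53 ± 0.36. CDX2, a caudal transcription factor, was at 26.9 ± 2.79 CPM in separate culture and 0.171 ± 0.296 in co-culture, and its call was lost without separate dox-free replicate 2 (adjusted p = 0.051) or 3 (adjusted p = 0.056). ARHGEF10 (-5.63 ± 0.63), CYB5D1 (-5.17 ± 1.11) and ZNF337 (-4.37 ± 0.68) were near 0 CPM in this co-culture group alone. The readthrough gene PTGES3L-AARSD1 (-6.95 ± 2.04) lost its call whichever library was left out, at adjusted p from 0.072 without separate dox-free replicate 3 to 0.10 without co-culture dox-free replicate 1, and with no filter (0.057). The assignment of reads between these and overlapping genes is not given in the sources used here.

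Of 24 tested glycolysis and hypoxia genes, 23 were higher, 0 lower and 1 did not pass (list alone 23 and 0), with a median of 0.96 (adjusted p = 4.9e-41). Members included SLC16A3, a lactate exporter, at 3.00 ± 0.084. The mitochondrially encoded mRNAs had 13 lower, 0 higher and 0 not passing of 13 tested (list alone 13 and 0), with a median of -1.87 (adjusted p = 1.6e-26). Members included MT-CO1 at -1.66 ± 0.094 and MT-CO2 at -1.66 ± 0.10. Mitochondrial genes took 5.88% ± 0.267 (SD) of counts in separate culture and 1.91% ± 0.0879 in co-culture, and the ribosomal RNAs MT-RNR1 and MT-RNR2 were at -0.42 ± 0.071 and -0.72 ± 0.061. Among DNA replication genes, 21 of 23 were lower, 0 higher and 2 did not pass (list alone 21 and 0), with a median of -0.95 (adjusted p = 4.9e-23). UHRF1 (-1.40 ± 0.063), the helicase subunit MCM4 (-1.13 ± 0.052) and the loader CDC6 (-1.22 ± 0.060) were lower. Of 28 tested ribosome biogenesis genes, 22 were lower, 3 higher and 3 did not pass (list alone 22 and 3), with a median of -0.99 (adjusted p = 5.3e-21). WDR43 (-1.28 ± 0.058), UTP20 (-1.79 ± 0.084) and NOP56 (-1.89 ± 0.092) were lower. The WNT targets had 11 lower, 0 higher and 3 not passing of 14 tested (list alone 11 and 0), with a median of -1.18 (adjusted p = 1.4e-18). The inhibitors NKD1 (-2.75 ± 0.085) and APCDD1 (-1.95 ± 0.093) were lower. Among cytosolic ribosomal protein genes, 36 of 40 were higher, 0 lower and 4 did not pass (list alone 37 and 0), with a median of 0.50 (adjusted p = 5.0e-13). The call was lost at adjusted p = 0.18 with an estimated correlation. RPLP1 (0.93 ± 0.066) and RPLP0 (0.72 ± 0.057) were higher.

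The definitive and extraembryonic endoderm genes (7 higher and 0 lower of 15, list alone 8 and 0, median 1.60) and the feeder fibroblast and matrix markers (10 higher and 1 lower of 18, list alone 10 and 2, median 0.36) were called higher. The interferon-stimulated genes (7 higher and 2 lower of 21, list alone 7 and 2, median 0.15) and the p53 targets (17 higher and 2 lower of 22, list alone 17 and 2, median 0.51) were called higher. The nuclear oxidative phosphorylation genes (14 higher and 1 lower of 26, list alone 16 and 1, median 0.28) and the NODAL and BMP targets (10 higher and 3 lower of 15, list alone 11 and 3, median 0.65) were called higher. The YAP targets (8 higher and 5 lower of 16, list alone 8 and 5, median 0.35) were called higher. The RNA sensing genes (9 lower and 2 higher of 20, list alone 9 and 3, median -0.25) and the ER unfolded protein response genes (11 lower and 1 higher of 18, list alone 11 and 1, median -0.32) were called lower. The heat shock genes (7 lower and 1 higher of 15, list alone 8 and 1, median -0.60) and the RNA decay genes (12 lower and 4 higher of 26, list alone 12 and 4, median -0.22) were called lower. The mitosis genes (16 lower and 3 higher of 22, list alone 17 and 4, median -0.44) were called lower. Camera gave these 12 lists adjusted p from 5.7e-09 to 0.014. Calls not held with an estimated correlation were at adjusted p of 0.18 for the feeder fibroblast and matrix markers, 0.096 for the RNA sensing genes, 0.15 for the interferon-stimulated genes, 0.057 for the ER unfolded protein response genes, 0.057 for the heat shock genes, 0.32 for the nuclear oxidative phosphorylation genes and 0.15 for the YAP targets. The test differed in sign from the median or mean for the RNA sensing genes (mean 0.10). The remaining 14 lists were not called, at adjusted p of 0.056 or more. The fixed genes POU5F1 (0.78 ± 0.11), NANOG (0.81 ± 0.053), ISG15 (0.62 ± 0.14) and COL1A1 (0.75 ± 0.12) were higher, and SOX2 (0.074 ± 0.061, adjusted p = 0.38), MAVS (-0.14 ± 0.086, adjusted p = 0.21) and ATF4 (-0.13 ± 0.067, adjusted p = 0.15) did not pass. ATF4 passed as lower without co-culture dox-free replicate 3 (adjusted p = 0.036), and SOX2 as higher with upper quartile normalization (0.047) and the filter of 10 CPM (0.034). In all, 10178 of 24165 genes passed, 5054 higher and 5124 lower, of which 2189 and 1501 changed at least 2-fold, with 48.6% to 57.4% higher over 4 scalings. With the filter of 10 CPM, the ER unfolded protein response (adjusted p = 0.18), RNA decay (0.071), YAP target (0.066) and endoderm (no adjusted p) lists lost their calls. Upper quartile normalization moved the median of all genes to 0.12.

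**Figure D3:**
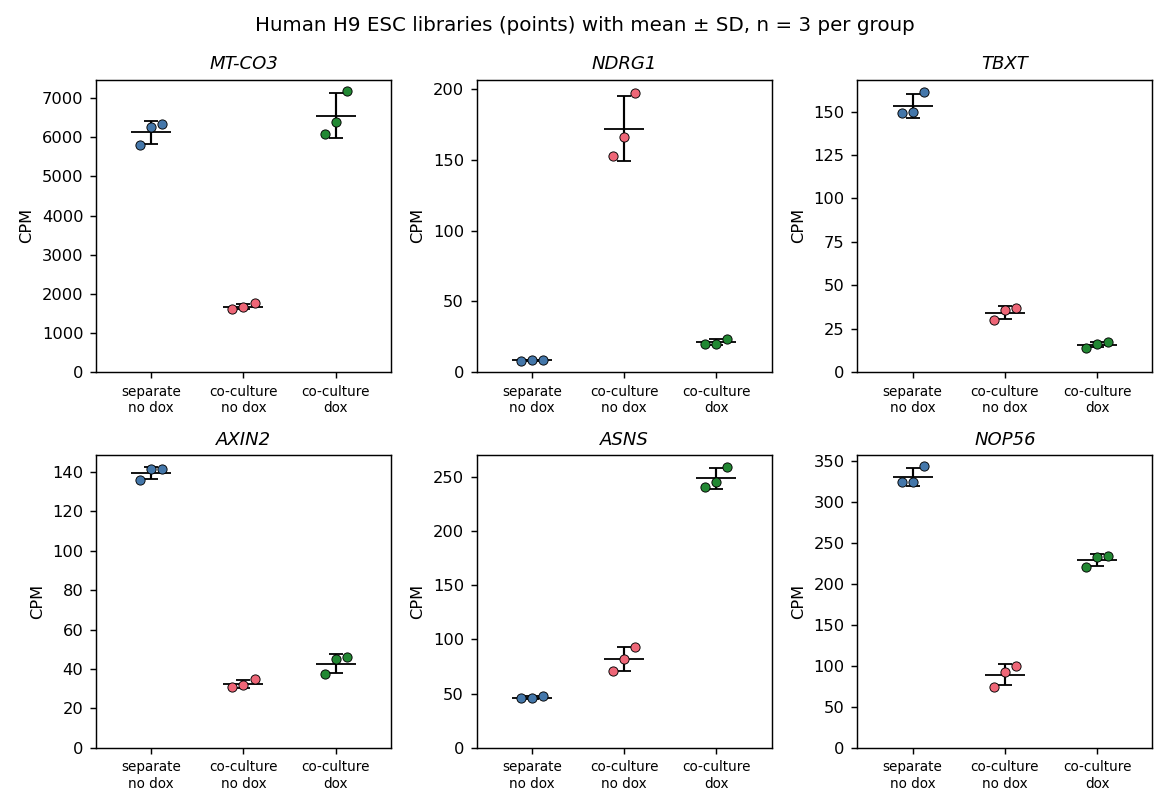
CPM (vertical axes) of MT-CO3, NDRG1, TBXT, AXIN2, ASNS and NOP56 in each human library, by group (horizontal axes), with points for libraries and the mean ± SD. MT-CO3 was at 6132 ± 295 CPM in separate culture, 1674 ± 73.0 in co-culture without dox and 6559 ± 569.7 in co-culture with dox.

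How human co-cultures with dox differed from those without was asked next. The mitochondrially encoded mRNAs were all higher with dox, MT-CO3 going from 1674 ± 73.0 to 6559 ± 569.7 CPM. Hypoxia and glycolysis genes fell, NDRG1 from 172 ± 22.9 to 21.0 ± 2.17 CPM and LDHA, lactate dehydrogenase, from 1328 ± 103 to 423 ± 23.0 CPM. Integrated stress response genes rose, with ASNS, asparagine synthetase, going from 81.9 ± 10.9 to 249 ± 9.44 CPM, and so did ribosome biogenesis genes such as NOP56, from 89.1 ± 13.02 to 229 ± 7.49 CPM. TBXT fell further, from 34.2 ± 3.62 to 15.8 ± 1.62 CPM.

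The largest increases included MT-ATP8 (2.89 ± 0.26), MT-CYB (2.66 ± 0.16), MT-ATP6 (2.50 ± 0.12) and MT-ND4L (2.45 ± 0.33), mitochondrial genes of which MT-ATP6 overlaps MT-ATP8 and all have nuclear copies, and FOSB (2.84 ± 0.34). ARHGEF10 (5.57 ± 0.63), CYB5D1 (4.97 ± 1.10) and ZNF337 (4.16 ± 0.67), near 0 CPM in the dox-free co-cultures, were also higher, but the call of CYB5D1 was lost without co-culture dox replicate 1 (adjusted p = 0.050), without co-culture dox-free replicate 1 (0.056) and with only these 6 libraries (0.077). The largest decreases were NRN1 (-4.55 ± 0.46), TMOD1 (-3.98 ± 0.73) and LOX (-3.97 ± 0.45), the natriuretic peptide NPPB (-3.58 ± 0.10), CCDC81 (-3.40 ± 0.28) and UPK1A (-3.32 ± 0.23) and the antisense P3H2-AS1 (-3.22 ± 0.35) and GATA6-AS1 (-3.15 ± 0.18). Of 13 tested mitochondrially encoded mRNAs, 13 were higher, 0 lower and 0 did not pass (list alone 13 and 0), with a median of 1.97 (adjusted p = 1.4e-52). Members included MT-CO2 at 1.94 ± 0.10. Their share of counts with dox was 6.15% ± 0.894 (SD), and MT-RNR1 and MT-RNR2 were at 0.36 ± 0.071 and 0.73 ± 0.061. The glycolysis and hypoxia genes had 21 lower, 1 higher and 2 not passing of 24 tested (list alone 22 and 1), with a median of -0.79 (adjusted p = 2.1e-52). Members included SLC16A3 at -2.81 ± 0.083. Among integrated stress response genes, 18 of 25 were higher, 0 lower and 7 did not pass (list alone 19 and 0), with a median of 0.78 (adjusted p = 1.5e-20). The cystine transporter SLC7A11 (1.57 ± 0.095) and CHAC1 (1.80 ± 0.12), a glutathione-degrading enzyme, were higher. Of 28 tested ribosome biogenesis genes, 22 were higher, 1 lower and 5 did not pass (list alone 22 and 2), with a median of 0.69 (adjusted p = 4.0e-20). NOLC1 (0.78 ± 0.054) and UTP20 (1.17 ± 0.082) were higher.

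The NODAL and BMP targets had 12 lower, 2 higher and 1 not passing of 15 tested (list alone 13 and 2), with a median of -1.001 (adjusted p = 3.0e-16). LEFTY1 (-1.29 ± 0.068), ID1 (-1.46 ± 0.079) and BAMBI (-1.001 ± 0.065) were lower. Among feeder fibroblast and matrix markers, 13 of 18 were lower, 0 higher and 5 did not pass (list alone 14 and 0), with a median of -1.01 (adjusted p = 4.6e-16). The collagens COL1A2 (-1.40 ± 0.048), COL5A1 (-1.91 ± 0.080) and COL6A1 (-1.12 ± 0.080) were lower. The core pluripotency genes (8 higher and 1 lower of 15, list alone 8 and 1, median 0.19) and the heat shock genes (6 higher and 1 lower of 15, list alone 9 and 1, median 0.37) were called higher. The RNA decay genes (9 higher and 0 lower of 26, list alone 9 and 3, median 0.16) and the cholesterol biosynthesis genes (8 higher and 3 lower of 22, list alone 10 and 5, median 0.16) were called higher. The DNA replication genes (21 higher and 1 lower of 23, list alone 22 and 1, median 0.56) and the mitosis genes (14 higher and 0 lower of 22, list alone 14 and 1, median 0.31) were called higher. The primitive streak and mesendoderm genes (11 lower and 2 higher of 18, list alone 12 and 2, median -1.63) and the definitive and extraembryonic endoderm genes (10 lower and 1 higher of 15, list alone 11 and 1, median -1.74) were called lower. The trophectoderm and amnion genes (4 lower and 1 higher of 13, list alone 5 and 1, median -0.37) and the interferon-stimulated genes (3 lower and 3 higher of 21, list alone 4 and 3, median -0.24) were called lower. The NF-kB targets (8 lower and 2 higher of 18, list alone 9 and 2, median -0.66) and the p53 targets (12 lower and 2 higher of 22, list alone 12 and 2, median -0.32) were called lower. The cytosolic ribosomal protein genes (17 lower and 1 higher of 40, list alone 20 and 1, median -0.15) and the FGF-ERK targets (8 lower and 4 higher of 16, list alone 10 and 4, median -0.28) were called lower. The YAP targets (8 lower and 2 higher of 16, list alone 10 and 2, median -0.29) were called lower. Camera gave these 15 lists adjusted p from 2.0e-15 to 0.048. With an estimated correlation, adjusted p was 0.094 for the trophectoderm and amnion genes, 0.17 for the interferon-stimulated genes, 0.061 for the NF-kB targets, 0.094 for the heat shock genes, 0.49 for the cytosolic ribosomal protein genes, 0.061 for the RNA decay genes, 0.094 for the cholesterol biosynthesis genes and 0.094 for the FGF-ERK targets. The remaining 11 lists were not called, at adjusted p of 0.083 or more.

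Among the fixed genes, SOX2 (0.47 ± 0.061) and ATF4 (0.65 ± 0.068) were higher and NANOG (-0.25 ± 0.053), CDKN1A (-0.72 ± 0.069) and COL1A1 (-1.02 ± 0.12) lower, and POU5F1 (-0.15 ± 0.11, adjusted p = 0.38), MAVS (-0.029 ± 0.086, adjusted p = 0.87) and ISG15 (-0.29 ± 0.14, adjusted p = 0.14) did not pass. POU5F1 passed as lower without co-culture dox-free replicate 1 (adjusted p = 0.022) and ISG15 without co-culture dox replicate 2 (0.030). In all, 6681 of 24165 genes passed, 3449 higher and 3232 lower, of which 569 and 1013 changed at least 2-fold, with 46.7% to 53.8% higher over 4 scalings. The call of the cholesterol biosynthesis genes was lost without co-culture dox replicate 1 (adjusted p = 0.051), without co-culture dox replicate 2 (adjusted p = 0.050) and without co-culture dox-free replicate 3 (adjusted p = 0.088). The filter of 10 CPM ended the calls of the RNA decay (adjusted p = 0.098), cholesterol biosynthesis (0.22) and endoderm (no adjusted p) lists. The human cells shared the dox-containing cultures, and no human group had dox without mouse cells.

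The human dox effect in co-culture ran against the co-culture effect. Of 5560 genes called in both comparisons, 5338 had opposite directions. Higher in co-culture and lower with dox were 2490 genes, against 676 for independent lists, and 2848 were lower and then higher, against 731. Both contrasts share the 3 dox-free co-culture libraries with opposite signs, which may give part of the excess. With no effect, in 20 simulations, at most 1 gene of either kind passed in both, and as many genes by smallest p as were called overlapped at means of 1533 and 1914. Across 24165 genes Pearson r was -0.655 (simulated -0.518 to -0.479), Spearman rho -0.669 and the covariance -1.61 (simulated -0.615 to -0.551). The simulations may lack the wider spread of the shared group, so they cannot size a reversal.

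Human cells in co-culture with dox were last compared with separate culture without dox. WNT-linked genes were among those furthest down: LEF1, a WNT-responsive transcription factor, was at -5.67 ± 0.24, CDX1 at -5.60 ± 0.29 and the ligand WNT3A at -5.61 ± 1.12. TBXT fell from 153 ± 6.74 to 15.8 ± 1.62 CPM. Higher were the peptide hormone APLN (3.58 ± 0.17), CHAC1 (3.42 ± 0.13), SHISA2 (3.07 ± 0.19) and CD48 (2.92 ± 0.27). CDX2 was at 26.9 ± 2.79 CPM in separate culture and 0.0622 ± 0.108 in co-culture, and its call was lost whichever library was left out, at adjusted p from 0.062 without co-culture dox replicate 1 to 0.070 without separate dox-free replicate 3.

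Of 14 tested WNT targets, 12 were lower, 0 higher and 2 did not pass (list alone 12 and 0), with a median of -1.77 (adjusted p = 4.6e-52). Among integrated stress response genes, 19 of 25 were higher, 2 lower and 4 did not pass (list alone 19 and 2), with a median of 0.67 (adjusted p = 5.7e-34). The primitive streak and mesendoderm genes had 12 lower, 3 higher and 3 not passing of 18 tested (list alone 12 and 3), with a median of -1.58 (adjusted p = 8.4e-29). Of 26 tested nuclear oxidative phosphorylation genes, 10 were higher, 0 lower and 16 did not pass (list alone 13 and 0), with a median of 0.21 (adjusted p = 4.1e-04). With an estimated correlation its adjusted p was 0.17. The RNA sensing genes had 5 lower, 2 higher and 13 not passing of 20 tested (list alone 5 and 2), with a median of -0.21 (adjusted p = 0.012). The call was lost at adjusted p = 0.13 with an estimated correlation. The p53 targets (9 higher and 2 lower of 22, list alone 13 and 2, median 0.23) and the cytosolic ribosomal protein genes (34 higher and 0 lower of 40, list alone 37 and 0, median 0.31) were called higher. The glycolysis and hypoxia genes (13 higher and 2 lower of 24, list alone 13 and 2, median 0.18) and the cholesterol biosynthesis genes (10 higher and 1 lower of 22, list alone 10 and 2, median 0.16) were called higher. The naive pluripotency genes (6 lower and 3 higher of 13, list alone 7 and 3, median -0.26) and the neuroectoderm genes (6 lower and 1 higher of 11, list alone 7 and 1, median -0.61) were called lower. The feeder fibroblast and matrix markers (7 lower and 1 higher of 18, list alone 9 and 1, median -0.58) and the ER unfolded protein response genes (12 lower and 1 higher of 18, list alone 13 and 2, median -0.39) were called lower. The heat shock genes (5 lower and 1 higher of 15, list alone 6 and 1, median -0.15) and the ribosome biogenesis genes (18 lower and 3 higher of 28, list alone 19 and 3, median -0.32) were called lower. The DNA replication genes (17 lower and 1 higher of 23, list alone 18 and 1, median -0.38) and the FGF-ERK targets (12 lower and 1 higher of 16, list alone 12 and 1, median -0.43) were called lower. Camera gave these 12 lists adjusted p from 1.8e-12 to 0.035. Adjusted p with an estimated correlation was 0.066 for the naive pluripotency genes, 0.16 for the neuroectoderm genes, 0.13 for the feeder fibroblast and matrix markers, 0.13 for the heat shock genes, 0.17 for the cytosolic ribosomal protein genes and 0.12 for the cholesterol biosynthesis genes. The remaining 15 lists were not called, at adjusted p of 0.063 or more.

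The fixed genes POU5F1 (0.63 ± 0.11), SOX2 (0.54 ± 0.061), NANOG (0.57 ± 0.053), CDKN1A (0.54 ± 0.069) and ATF4 (0.52 ± 0.068) were higher, and MAVS (-0.17 ± 0.086, adjusted p = 0.18), ISG15 (0.33 ± 0.14, adjusted p = 0.11) and COL1A1 (-0.27 ± 0.12, adjusted p = 0.12) did not pass. ISG15 passed with the filter of 10 CPM (adjusted p = 0.039), and COL1A1 passed as lower by DESeq2 (0.045) and with only these 6 libraries (0.038). In all, 5900 of 24165 genes passed, 2835 higher and 3065 lower, of which 803 and 537 changed at least 2-fold, with 45.8% to 57.8% higher over 4 scalings. The call of the neuroectoderm genes was lost without co-culture dox replicate 2 (adjusted p = 0.080). The filter of 10 CPM ended the calls of the RNA sensing (adjusted p = 0.058) and neuroectoderm (no adjusted p) lists.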

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

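The tests of the fibroblast and matrix markers were chosen after the result was seen. The interaction, its lists and the reassigned dox labels were chosen before.

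The dox effect on mouse cells differed between co-culture and separate culture for 2054 genes by the interaction test. With the dox labels reassigned within each culture, 1 of 100 drawn assignments gave as many genes, the real one, and the highest other gave 1724. The assignments drawn, 100 of 200 possible, also break up the dox effects themselves, so they cannot say whether chance gave the interaction. Of those drawn, 0 mirrored the labels of 1 culture alone, which would turn the interaction into the sum of the dox effects. Of 62 named genes of the dox comparisons, 44 passed, of which 40 are given here, with interaction log2 fold changes in parentheses and standard errors of 0.061 to 0.72 (n = 3 per group). Above 0 in co-culture against separate culture were the squamous genes Sprr2a2 (3.09) and Sprr2a1 (3.09), the mesoderm and WNT-linked factors T (2.29) and Sp5 (2.75) and the YAP targets Ccn1 (0.84), Ccn2 (0.62) and Amotl2 (0.87). So were the sterol gene Hsd17b7 (0.85), the interferon-linked genes Bst2 (0.69) and Isg15 (0.70) and the cilium genes Cfap65 (1.61), Cfap95 (1.08), Dnaaf11 (1.55) and Drc7 (1.35). The others above 0 were Arg1 (3.11), Pomc (1.08), Id2 (1.03), Irx3 (0.73), Grin1 (0.74), Foxa2 (0.63), Atf4 (0.35) and Cdkn1a (0.33). Below 0 were the NODAL pathway genes Lefty2 (-4.27), Lefty1 (-2.92) and Tdgf1 (-1.73), the collagens Col1a2 (-1.60) and Col1a1 (-0.83) and the NF-kB targets Ccl2 (-1.18), Tnfaip3 (-0.73) and Csf1 (-0.69). The others below 0 were Tfpi2 (-4.18), Marco (-3.29), Tuba8 (-2.82), Olr1 (-2.59), Gata4 (-2.45), Galnt6 (-1.60), C3 (-0.67), Eomes (-0.61), Nanog (-0.57) and Ndrg1 (-0.29). The macrophage markers, a list added, were lower here too (median -0.83, adjusted p = 4.1e-08). Marco lay near the floor, and the calls of Isg15 and Cdkn1a were lost when single libraries were left out.

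By camera, 13 lists differed between the cultures in their dox effect, with the median interaction log2 fold change in parentheses. Called higher in co-culture were the mitochondrially encoded mRNAs (0.63), the WNT targets (0.33), the neuroectoderm genes (0.31) and the interferon-stimulated genes (0.30). Called higher too were the cholesterol biosynthesis genes (0.20), the integrated stress response genes (0.20), the FGF-ERK targets (0.16) and the YAP targets (0.044). Called lower were the definitive and extraembryonic endoderm genes (-0.93), the NODAL and BMP targets (-0.74), the feeder fibroblast and matrix markers (-0.66), the NF-kB targets (-0.12) and the core pluripotency genes (0.0038), the last with a median above 0. Adjusted p, with the correlation estimated, was 0.057 for the core pluripotency genes, 0.057 for the neuroectoderm genes, 0.36 for the mitochondrially encoded mRNAs and 0.13 for the YAP targets.

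Some lists moved in opposite directions in the 2 species, with the list mean of every library of a group beyond those of the other group. The difference between species was not tested. In co-culture without dox, the human median against the mouse median was opposite for the p53 targets (0.51 against -0.18), the mitosis genes (-0.44 against 0.37) and the YAP targets (0.35 against -0.34). With dox in co-culture it was opposite for the core pluripotency genes (0.19 against -0.22), the feeder fibroblast and matrix markers (-1.01 against 1.40) and the p53 targets (-0.32 against 0.35). The same held with dox for the mitosis genes (0.31 against -0.26), the FGF-ERK targets (-0.28 against 0.40) and the YAP targets (-0.29 against 0.66). With the correlation estimated, the human calls were lost for the YAP targets without dox (adjusted p = 0.15) and the FGF-ERK targets with dox (0.094).

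The mouse fibroblast and matrix markers rose with dox, and feeder cells, which are mouse cells, could bring these RNAs to the mouse table. A larger share of feeder RNA of 1 fixed makeup was argued against: 9 of 20 markers lay over 3 standard errors from the common multiple of 0.651 that relates the gain in co-culture to that in separate culture. Col3a1 gained 95.7 CPM in separate culture and 96.1 in co-culture, Dcn 41.8 and 2.58. A change in the feeders' own expression stays open, and 18 of the human orthologs passed the filter in the human cells, so stem cells may express the genes too. Dox and the induced Cas13 cannot be told apart, since 0 mouse libraries had dox without an inducible Cas13.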

How the results depend on the processing

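Counts divided by 4 and library totals alone were tests chosen after the data were seen, the others before. Under every alternative but the test against a fold of 1.5, the count of called genes stayed within 1.5 times its value: 5244 to 7344 for mouse dox in separate culture, 5083 to 7493 for mouse dox in co-culture, 5762 to 8020 for mouse co-culture without dox, 5191 to 7389 for mouse co-culture with dox, 1430 to 2904 for the interaction, 7406 to 11111 for human co-culture without dox, 5374 to 7639 for human dox in co-culture and 4303 to 6943 for human co-culture with dox. Against a fold of 1.5, the counts in the same order were 1668, 1616, 1184, 1041, 309, 3694, 1182 and 843. The share of calls that were higher is given with each comparison over 4 scalings (TMM, DESeq2's, upper quartile and library totals). Against a fold of 1.5 it was 35.4% for mouse co-culture without dox, 33.8% for mouse co-culture with dox and 34.9% for human dox in co-culture. In the usual test without co-culture dox-free replicate 2, the last was 57.0%. The lists called with an estimated correlation were 6 for mouse dox in separate culture, 13 for mouse co-culture with dox, 10 for human co-culture without dox, 13 for human dox in co-culture and 9 for human co-culture with dox. By fry, which does not compare a list with other genes, they were 23 for mouse dox in separate culture, 27 for mouse co-culture without dox, 30 for human co-culture without dox and 28 for human co-culture with dox.

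The r between the mouse dox effects (0.333) was 0.322 by DESeq2, 0.687 with the filter of 10 CPM and 0.246 to 0.263 without 1 library. The r of the human relation (-0.655) was -0.750 with that filter, -0.769 without co-culture dox-free replicate 3 and -0.537 without co-culture dox replicate 3. Genes tested may differ, and no cause was tested. Of 259 results on named genes, 204 kept their direction and their side of the threshold under every alternative that gave a value, and none reversed. Losses of a call numbered 46 against a fold of 1.5, 34 over all fits with 1 library left out, 3 with the replicate block, 2 with no filter, 2 with library totals alone and 1 with only the groups compared. Gains numbered 4 with the stricter filter, 4 with 1 library left out, 2 by DESeq2 and 1 each under 4 others.

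With the replicate block, the counts of called genes in that order were 6360, 6298, 6810, 6171, 1735, 10293, 7209 and 6553. That block ended the calls of Cdkn1a in the interaction (adjusted p = 0.051), of PTGES3L-AARSD1 in human co-culture without dox (0.073) and of CDX2 with dox (0.051), and called COL1A1 there (0.0088). It ended the list calls of the human interferon-stimulated genes without dox (0.098) and with dox in co-culture (0.14), the human YAP targets without dox (0.11) and the naive pluripotency genes with dox against separate culture (0.071). Changes of 1.5-fold were recovered in 16.4% of simulated genes for the interaction.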

Other observations

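The lists of cilium, axis, macrophage and immediate early genes, the tests of these patterns and of the mitochondrial mRNAs, and the test of reads at 1% of their own level were chosen after the results were seen. The other splits and the test of shares were chosen before.

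Motile cilium genes fell with dox in mouse cells, 38 of 41 in separate culture (median -2.25, adjusted p over the lists added = 1.5e-51) and 36 of 41 in co-culture (median -1.30, adjusted p = 8.2e-25). The fall was smaller in co-culture, with an interaction higher for 17 and lower for 0 (median 0.74, adjusted p = 9.1e-12). Posterior and caudal axis genes rose with dox on balance, 12 higher and 3 lower of 25 in separate culture and 12 and 2 in co-culture, with medians of 1.90 (adjusted p = 5.4e-05) and 2.06 (adjusted p = 2.9e-07), and an interaction higher for 9 and lower for 2 (median -0.072, adjusted p = 0.019). In human co-culture 11 were lower and 2 higher of 21 without dox (median -3.25, adjusted p = 0.083) and 12 and 2 with dox (-3.19, 6.3e-11). FGF17 and CYP26A1 rose, and several HOX genes lay near the floor. Between co-cultures dox went with 1 higher and 8 lower (-0.96, 9.3e-05). With dox in co-culture, 19 of 23 mouse immediate early genes were higher and 2 lower (median 0.92, adjusted p = 5.5e-21). In separate culture 3 were higher and 10 lower (median -0.23, adjusted p = 0.013, 0.11 with an estimated correlation), with an interaction higher for 17 and lower for 2 (median 1.07, adjusted p = 1.6e-51).

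Mouse co-cultures had lower macrophage markers and immediate early genes, the latter lower for 22 of 23 without dox (median -3.17) and 23 of 23 with it (median -2.23). Lyz2, the lysozyme abundant in macrophages, was at 348 ± 90.4 CPM in separate culture and 25.2 ± 1.66 in co-culture without dox. The fibroblast markers' median lay at least 3.39 above the macrophage markers', but stem cells may express the former, so a smaller feeder share stays open. For the immediate early genes, a handling difference in co-cultures of both species could give part of the fall. The human median was -0.88 without dox (14 lower and 2 higher of 23, adjusted p = 1.4e-05, 0.073 with an estimated correlation). With dox it was -1.30 (adjusted p = 1.2e-15), both falls smaller than in mouse. Signalling between the species stays open and was not tested. A sorting step that removed macrophages cannot be told apart from the co-culture, since the labels set 0 co-culture libraries apart by one.

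Human mitochondrial mRNAs were lower in co-culture without dox and not with it. Library scaling was argued against, as the median nearest 0 over 4 normalizations was -1.78. Loss of human mitochondrial reads to the mouse genome in every co-culture library was argued against by a median of 0.030 in co-culture with dox. Dox acting on mitochondrial RNA without the mouse cells cannot be told apart, as 0 human libraries had dox in separate culture, and a response to the mouse cells may remain as a hypothesis.

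Reads of 1 species might be counted in the other's table. Of 16 mouse genes under 0.5 CPM in separate culture whose human namesake was at 50 CPM or more, 1 gained 0.5 CPM in co-culture, against 44 of 3367 with a namesake under 0.5 CPM. The difference of 4.94 percentage points (-1.57 to 17.7, 95% bootstrap interval) left human reads in the mouse table undecided. Of the human genes alike, 2 of 12 gained, against 142 of 3601, and the difference of 12.7 points (-4.28 to 37.6) left mouse reads undecided too. The median gain was -0.0024% of the namesake's CPM in mouse (upper bound 0.0711%) and 0.0163% in human (0.0209%). This argues against 1% or more at the median, not in each gene.

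The 6 libraries of each comparison of 2 groups can be divided in 10 ways, too few for a share under 0.05, and 1 of them, the real one, gave the most genes each time. With only these libraries in the fit and the comparisons in the order of the text, the real division gave 6623, 6404, 7839, 5857, 10132, 5650 and 6943 genes and the highest other 0, 0, 1, 0, 0, 1 and 0.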
